A study of Homo sapiens with 4 samples.

How the data were processed

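Single-cell RNA was measured with 10x Chromium Next GEM 3′ v3.1 kits in 4 libraries of 1 human iPSC line: day 8, day 26 and 2 at day 60 (experiments 1 and 2). Per the labels' protocols, aggregates of 3500 cells were treated with BMP-4, FGF2 and SB-431542, then LDN193189 with FGF2, then CHIR99021, and moved to otic maturation medium. Organoids were dissociated with Accutase and DNase, gated for live cells, sorted for EPCAM at day 26 and day 60, and loaded at 17200 cells with a target of 40000 reads per cell. Experiments 1 and 2 were tied to libraries 1 and 2 by number only.

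The deposited files hold counts of UMIs per gene and barcode for 21570 genes. Per the file headers, the counts were made with Cell Ranger 6.1.2 (day 8 and day 26) and 7.0.0 (both at day 60), while the submitters' processing notes give 6.1.2 for all, with alignment to GRCh38.p13 and Seurat for later steps. Whether reads in introns were counted is not given in the sources used here. Tested on the files, every barcode had at least 500 UMIs, so a filter had been applied by the authors. The authors' cell names and clusters were not used here. Day 8 held 20987 barcodes, more than the 17200 cells loaded, and the others 16195, 9103 and 8218. Median genes per barcode were 3914, 3471, 3059 and 1851 and median mitochondrial shares 2.73, 1.77, 5.39 and 5.09%.

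Barcodes with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs were kept (18339, 14900, 6324 and 6800). The mitochondrial limit alone removed 7.11, 2.41, 19.78 and 13.31% of barcodes. Doublets were scored per library with a rewrite of the Scrublet method, and scores above 0.25 were removed (9.07, 5.77, 0.66 and 1.31%). This limit was set after the scores were seen, since the automatic limit marked 5.83, 3.09, 0.0 and 0.0%. Of simulated doublets 61.8, 41.9, 6.0 and 13.1% scored above it, so doublets at day 60 mostly stay in.

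Each library was clustered alone (counts scaled to 10000 per cell, log, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1, fixed seed). Clusters were named from 20 marker lists: a class needed at least 4 markers, each detected in at least 10% of the cluster's cells, a score of at least 0.25 and no other class with more markers among the 10 genes highest by fold. Clusters under 30 cells stayed without a name, as did those whose median UMIs lay more than 3 times below the library's and whose top genes held no marker of the class. The markers were written before the data were examined, as were the groups, comparisons, size rules and the first set of alternatives. The naming limits were set after the clusters were seen. Cells of a class were summed per library when at least 50 were present. Otic-like sums held 65319690, 81657867, 5323531 and 708707 UMIs, so 1 UMI is 0.0153, 0.0122, 0.188 and 1.41 CPM.

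Comparisons were day 26 over day 8 and day 60 over day 26 in otic-like and epidermis-like cells, day 26 over day 8 in neuroblast-like cells, and day 60 experiment 2 over experiment 1 in otic-like cells. Differences are on the scale of log2(CPM + 1). A gene entered at 10 CPM or more in any sum compared and counted as higher or lower at a log2 difference of 2, in both day 60 libraries where they take part. With 1 library at day 8 and day 26 no test or standard error was given for these. Intervals are 95% Clopper-Pearson (shares) or exact Poisson (sums and ratios). A gene at 0 was set against a floor of 3 counts per library. On simulated counts the size rule found 100% of genes at a log2 of 3, 94 to 100% at 2.5 and 0% at 1. It called 4 unchanged genes in experiment 2 over 1 and 0 elsewhere. These counts had Poisson error alone, without spread between libraries, and the genes changed lay well above the entry limit. They thus give no rate of false calls between real libraries.

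Gene groups were 21 fixed lists (placodal transcription factors, otic vesicle, prosensory and supporting cell, hair cell, otoconial and tectorial matrix, endolymph ion transport, dorsal and ventral otic patterning, WNT, FGF and BMP response, NOTCH pathway, cell cycle, neuroblast, pluripotency, basal and suprabasal epidermis, simple epithelium, mesenchyme, hypoxia and glycolysis, dissociation and heat shock). Members needed 1 CPM and counted as higher or lower at 2-fold. Each median was placed among 10000 random lists of matched expression, which describes these libraries and is no test of replicates.

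Genes named are all list members, and those with the highest and lowest differences among genes of at least 50 CPM in the higher sum: 10 each for otic-like stage comparisons and 5 each for the others. Day 60 genes were ranked by the smaller of their 2 differences. Mitochondrial, ribosomal protein, X-inactivation, Y-linked and clone-named genes were left out, and a few genes that the rule names are not reported here. Detection of EPCAM, SOX2 and MKI67 was read after thinning each cell to 2000 UMIs. Identifiers and spans come from GENCODE 29, which matched 21431 genes (99.4%).

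Alternatives covered cell filters, doublets, Leiden resolution, joint clustering, naming per cell, pseudocount, low-value filter, TMM, mean CP10k, all kept cells in place of the class, leaving out each day 60 library, and edgeR and DESeq2. A correction for gene span, leaving out low-mitochondrial cells, a shallow cluster or cells with suprabasal UMIs (KRT10 counted or not), counting cells with at least 6 hair cell markers, adding to a class the unnamed clusters nearest to it, lists without class-naming members, and the alternatives for experiment 2 over 1 were chosen after seeing the data. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Simulated changes of log2 3 and 2 were found in 100 and 93% of cases by edgeR and 97 and 80% by DESeq2. edgeR called 4 unchanged genes and DESeq2 0. All these simulated libraries came from the day 26 profile with a fixed spread, and the genes changed lay well above the entry limit. They thus give no rate of true or false calls for the real day 60 pair.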

Results

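The series holds 10x Chromium 3′ single-cell RNA counts from organoids of a human iPSC line (WTC11 with a SOX2-GFP reporter) grown toward inner ear. It has 1 library at day 8, 1 at day 26 and 2 at day 60. Per the labels' protocols, day 8 cells came from 200 organoids as live, otherwise unsorted cells, and day 26 cells from 100 organoids after sorting for the epithelial surface protein EPCAM. Day 60 cells were also EPCAM-sorted, from 48 unselected organoids (experiment 1) and from 8 organoids chosen for SOX2-GFP-bearing vesicles (experiment 2). That library 1 is experiment 1 rests on the numbers in the labels alone. After filtering and doublet removal 16675, 14041, 6282 and 6711 cells remained for day 8, day 26, and day 60 experiments 1 and 2. Before filtering the libraries held 306362873, 195483006, 95884565 and 41759697 UMIs, with medians of 13311, 11254, 8014 and 4683 UMIs per barcode. Sort, depth and the Cell Ranger version in the file headers thus differ between stages as well as age. The version was 6.1.2 at day 8 and day 26 and 7.0.0 at day 60, so it cannot be told apart from stage in day 60 over day 26. With 1 library at day 8 and at day 26, no difference from either has a replicate check. Intervals on single libraries are 95% counting error only (exact binomial for shares, exact Poisson for sums), and day 60 values are mean ± SD with n = 2 or given per library (experiment 1, then 2). A list median given alone for day 60 is that of the members' mean differences.

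Which cell types make up the organoids at each stage? Cells with placodal and otic epithelial markers formed 26.2% of the day 8 library (25.5 to 26.8), 40.5% of the day 26 library (39.6 to 41.3) and 4.21 ± 4.13% of the day 60 libraries (7.13 and 1.30%). Epidermis-like cells, which express keratins and other barrier genes, had no named cluster among 16675 cells at day 8, made up 7.83% at day 26 (7.39 to 8.28) and 43.8 ± 35.6% at day 60 (18.6 and 68.9%). Neuroblast-like cells, the precursors of inner ear and other placodal neurons, were 0.966% at day 8 (0.823 to 1.13) and 5.45% at day 26 (5.08 to 5.84), and no day 60 cluster bore the name. Names go to clusters of at least 30 cells, so a missing name sets no limit on scattered cells. Hair cell-like cells, the mechanosensory cells of the ear, formed a named cluster in day 60 experiment 1 alone, of 65 cells or 1.03% (0.799 to 1.32). With the libraries clustered together no cluster bore the name, and naming cell by cell gave 89, 290, 113 and 29 such cells at day 8, day 26 and in day 60 experiments 1 and 2. Cells with at least 6 of 16 hair cell markers made up 0.018, 0.399, 1.58 and 0.164% of these libraries.

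Experiment 1 at day 60 held many cell types outside the ear: mesenchyme-like cells at 22.5%, skeletal muscle-like at 11.0%, central neuron-like at 8.20% and neural epithelium-like at 6.08%. It also held smaller groups with genes of ciliated or ependymal cells (2.31%), retinal pigment or choroid plexus (2.26%), neural crest and glia (1.66%), chondrocytes (0.987%) and melanocytes (0.541%). Experiment 2 held epidermis-like cells, 1.31% mesenchyme-like cells and 1.04% amnion-like cells beside its few otic-like cells. Among its unnamed clusters, cluster 16 (84 cells, 1.25%) scored nearest to chondrocytes (3.87). Cluster 12 (171 cells, 2.55%) scored nearest to hair cells (1.96) but had muscle and choroid plexus genes among its top genes. Fewer named types there thus do not mean that other cell types were missing. At day 8 the other named groups were neural crest and glia-like (13.2%), amnion-like (9.60%) and neural epithelium-like cells (4.93%), and at day 26 mesenchyme-like (2.41%) and neural epithelium-like cells (1.50%).

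The otic-like class held clusters 2, 6, 7 and 11 at day 8 and clusters 2, 3, 4, 6, 9, 10 and 16 at day 26, but a single cluster in each day 60 library (448 and 87 cells). Epidermis-like cells made up 4 clusters in experiment 1 and 10 in experiment 2. The day 26 epidermis-like class rests mainly on cluster 8, whose median depth (3077 UMIs) was 0.26 of its library's. Clusters without a name held 45.1, 42.4, 17.7 and 27.4% of cells. They include day 8 clusters that scored nearest to pluripotent (9.37%) or amnion cells (10.8%) without reaching the class. At day 26 clusters 0, 1, 7 and 12, which reached no class, held 27.5%, and clusters 0 and 1 (1372 and 1232 cells) have the stress genes GDF15 and TRIB3 among their top genes. Day 26 clusters 5 (7.02%) and 18 (2.26%) scored nearest to otic-like and neuroblast-like cells but stayed unnamed. In experiment 2 clusters 2 and 5 (16.8%) and the shallow cluster 9 (5.59%) were nearest to epidermis. Some named epidermis-like clusters carry stress or immune genes on top, namely cluster 3 of experiment 1 (GDF15, S100A8, S100A9) clusters 7 and 11 of experiment 2 (the hypoxia gene CA9) and cluster 6 of experiment 2 (the airway genes LCN2 and SCGB1A1). The larger muscle-like cluster of experiment 1 (418 cells) had a median of 1322.5 UMIs. The cluster names were rebuilt here from marker lists, so a share may differ from one under the authors' own names. Naming cell by cell put the day 8 otic-like share at 4.08% and the day 26 share at 30.7%. Over other settings the day 26 epidermis-like share ran from 2.64 to 10.8% and the day 60 otic-like mean from 1.41 to 4.37%.

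**Figure D1:**
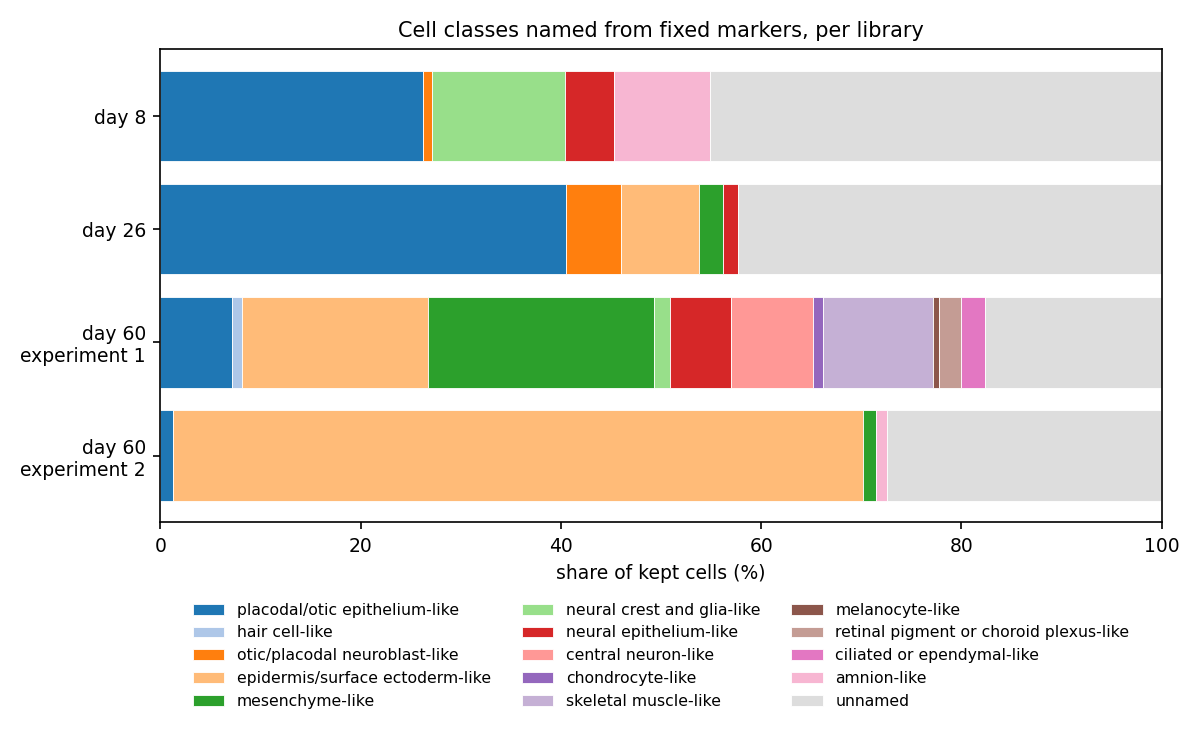
Share of kept cells (percent, horizontal axis) in each marker-named cell class, one bar per library (day 8, day 26, day 60 experiments 1 and 2). Otic-like cells have their largest share at day 26, and epidermis-like cells fill most of experiment 2.

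How far do transcripts of EPCAM, SOX2 and MKI67 follow the sort, the reporter and cell division? With every cell thinned to 2000 UMIs, EPCAM was detected in 34.2% of cells at day 8, 48.1% at day 26, and 11.5 and 34.4% in day 60 experiments 1 and 2 (unthinned 65.8, 80.7, 27.6 and 58.0%). The EPCAM-sorted experiment 1 thus had the lowest detection of all libraries. Its otic-like cells reached 48.5%, while its mesenchyme-like cells, which should lack the gene, stood at 4.21% (median depth 14866.5 UMIs) and its muscle-like cells at 2.12%. SOX2, which marks neural and prosensory progenitors, was detected in 7.75, 17, 14.1 and 14.6% of otic-like cells in that order (unthinned 37.2, 54.5, 39.1 and 36.8%), against 2.34% of day 26 and 4.00% of experiment 1 mesenchyme-like cells. Over all cells SOX2 was found in 0.883% in experiment 2, whose organoids were picked for SOX2-GFP, and in 11.3% in experiment 1.

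The proliferation gene MKI67 was detected in 23.4% of day 8 otic-like cells (22.1 to 24.7), 9.93% at day 26 (9.15 to 10.7), and 0.941% (0.257 to 2.39) and 2.44% (0.297 to 8.53) at day 60. Unthinned these shares were 49.8, 26.4, 3.12 and 2.30% at median depths of 13373.5, 13812, 10059.5 and 6162 UMIs. In neuroblast-like cells the share was 10.7% (6.35 to 16.6) at day 8 and 18% (15.3 to 21) at day 26 (unthinned 26.1 and 37.4%). These intervals overlap, and the unnamed cluster 18 of day 26 is not among these cells. Amnion-like cells at day 8 (1.51%), neural epithelium-like cells at day 26 (2.97%) and central neuron-like cells at day 60 (0.6%) mark the low end. Thinning left out 750, 809, 550 and 707 shallower cells.

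What separates otic-like cells of the vesicle stage (day 26) from those of the placode stage (day 8)? Day 26 cells carried more of the otoconial and tectorial matrix genes, which build the extracellular layers over sensory patches, and of part of the otic vesicle genes. They had lower levels of pluripotency, FGF response and cell cycle genes. OTOL1 (ENSG00000182447), which encodes an otoconial collagen-like protein, went from 0 to 431 CPM (at least 9381-fold), and OC90, the main otoconial matrix protein, from 0 to 69.7 CPM (at least 1517-fold). The roof-side otic transcription factor LMX1A (ENSG00000162761) went from 0.107 to 468 CPM (4371-fold, 2121 to 10872). Day 8 clusters took the otic-like name at scores of 0.32 to 0.5 and day 26 clusters at 0.57 to 1.21. The limit of 0.25 was set after the clusters were seen. At day 8 neural epithelium-like cells held more LMX1A (13.1 CPM) than otic-like cells. The contrast is thus not set apart from a difference in which cells bear the name. Of 10150 genes that entered, 871 were at least 4-fold higher and 173 at least 4-fold lower at day 26 (83.4% of the 1044 higher).

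Long genes stand behind much of that count. The longest 10% of genes (span of at least 198 kb) held 465 of the 869 higher genes with a known span (53.5%) and 6 of 173 lower ones (3.47%). Genes of at least 200 kb took 10.4% of UMIs in day 26 otic-like cells, and 3.26 to 3.58% in day 8 classes. The longest 10% were shifted by 1.94 log2 in otic-like cells (1.80 to 2.08) and by 1.45 (1.35 to 1.57) in neural epithelium-like cells, so the shift is not confined to otic-like cells. After taking out the median shift per span group 721 genes passed (481 higher, 240 lower, 66.7% higher).

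Among the highest genes the axon guidance receptor gene DCC (ENSG00000187323) went from 0.0919 to 1637.6 CPM (log2 of CPM + 1 10.55; 17827-fold, 8190 to 48579). It was followed by CCSER1 (9.70), the transcription factor gene NFIA (9.10; 695-fold, 613 to 790), OTOL1 (8.75), LMX1A (8.73), IL1RAPL1 (8.52), ERBB4 (8.12), ADAMTSL1 (8.05), DLGAP1 (8.05) and DCLK1 (7.90). All of these but OTOL1 and LMX1A lie in the longest 10%. With the span shift taken out DCC stood at 8.74, NFIA at 7.29, OTOL1 at 9.06 and LMX1A at 8.03. When the day 26 otic-like cells were clustered again, DCC led a subcluster of 469 cells that the rule named olfactory placode-like (score 0.7). It also led a subcluster of 256 cells that kept the otic-like name, while subclusters of 237 and 175 cells got no name. The lowest were the tight junction gene CLDN10 (ENSG00000134873; 486 to 0.612 CPM, 794-fold, 602 to 1071), the RNA-binding pluripotency gene LIN28A (ENSG00000131914; 296 to 0.661 CPM, -7.48), HAPLN1 (-7.10), the FGF ligand genes FGF3 (64.3 to 0.049 CPM, -5.96) and FGF8 (71.0 to 0.269 CPM, -5.82), HAS2 (-5.66), LGI1 (-5.65), L1TD1 (-5.61), CYP1B1 (-5.54) and EDN1 (-5.38).

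The otic vesicle list had a median of 1.77, above all but a few of 10000 random gene lists of the same expression (percentile 100.0), with 9 members at least 2-fold higher and 3 lower. TBX2 (0.536 to 211 CPM, 7.11), SOX10 (1.09 to 85.3 CPM, 5.37), COL9A2 (4.07) and FBXO2 (48.9 to 232 CPM, 2.23) were higher, and SPARCL1 (392 to 17.7 CPM, -4.4) and BMP4 (126 to 5.22 CPM, -4.35) lower. Of its 14 members 8 also named the class, and without them the median was 0.53. The otoconial and tectorial matrix list had the largest median, 4.20 (8 of 12 members higher, 2 lower, percentile 100.0; 4.33 without its 3 naming members). Beside OTOL1 and OC90 it held OTOGL (0.26 to 130 CPM, 6.70), COL9A3 (10.7 to 446 CPM, 5.26), OTOA (1.93 to 60.9 CPM, 4.4) and OTOG (4.33). Dorsal patterning genes had a median of 0.91 (5 higher, 1 lower; 0.64 without the naming members), with WNT2B (4.44) and DLX6 (4.63) higher. Ventral genes split around a median of 0.38, FST (3.77) and EMX2 (3.02) higher and OTX2 (-4.37) lower.

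Placodal transcription factors split, with a median of -0.05 (6 higher, 5 lower; -0.85 without the 8 members that name the class). EYA4 (0.245 to 123 CPM, 501-fold, 308 to 877), EYA1 (39.9 to 382 CPM, 3.23), PAX2 (1.24 to 41.1 CPM, 4.23) and DLX5 (48.6 to 208 CPM, 2.07) were higher. The early ectodermal genes FOXI3 (46.7 to 0.992 CPM, -4.58), TFAP2A (247 to 26.1 CPM, -3.19) and SOX3 (-4.05) were lower. FGF response genes had a median of -0.74 (5 of 12 lower, 1 higher, percentile 0.23), with SPRY1 (241 to 51.6 CPM, -2.20), SPRY4 (-2.39) and ETV4 (-2.96) lower. Cell cycle genes had a median of -1.06 (9 of 16 lower, none higher), with MKI67 (-1.64), CENPF (686 to 246 CPM, -1.48) and TOP2A (-1.28). Pluripotency genes stood at -2.88 (5 of 6 lower).

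Prosensory genes as a group hardly differed (median -0.29, 4 higher, 2 lower), though S100A1 (8.80 to 1785.4 CPM, 7.51), FGF20 (4.56) and SOX2 (46.0 to 103 CPM, 1.14) were higher. The few hair cell genes present had a median of 0.66 (3 of 8 higher), with PCDH15 at 5.75 and ESPN at 4.04, and ATOH1, the hair cell master regulator, had no count at either stage. Medians were 0.17 for endolymph ion transport (KCNQ1 5.27, GJB6 -2.68), 0.45 for WNT response, -0.12 for BMP response, -0.38 for NOTCH pathway (DLL1 -3.01) and 0.94 for neuroblast genes. Epithelial genes moved in opposite ways: basal epidermis 1.36 (KRT17 3.33), suprabasal epidermis 0.77, simple epithelium -0.75 (KRT8 -1.44, KRT18 -2.01). Mesenchyme genes, which mark another cell type, stood at -0.72. Hypoxia genes (1.40; BNIP3 97.2 to 414 CPM, 2.08) and dissociation genes (1.02; FOS 40.0 to 441 CPM, 3.43, and EGR1 3.09) were both higher at day 26, the stage that was also sorted. List medians moved little when span was taken out, to 1.49 for the otic vesicle and 4.03 for the otoconial list. With a pseudocount of 10 CPM 423 genes passed, and with genes of at least 50 CPM only, 504.

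**Figure D2:**
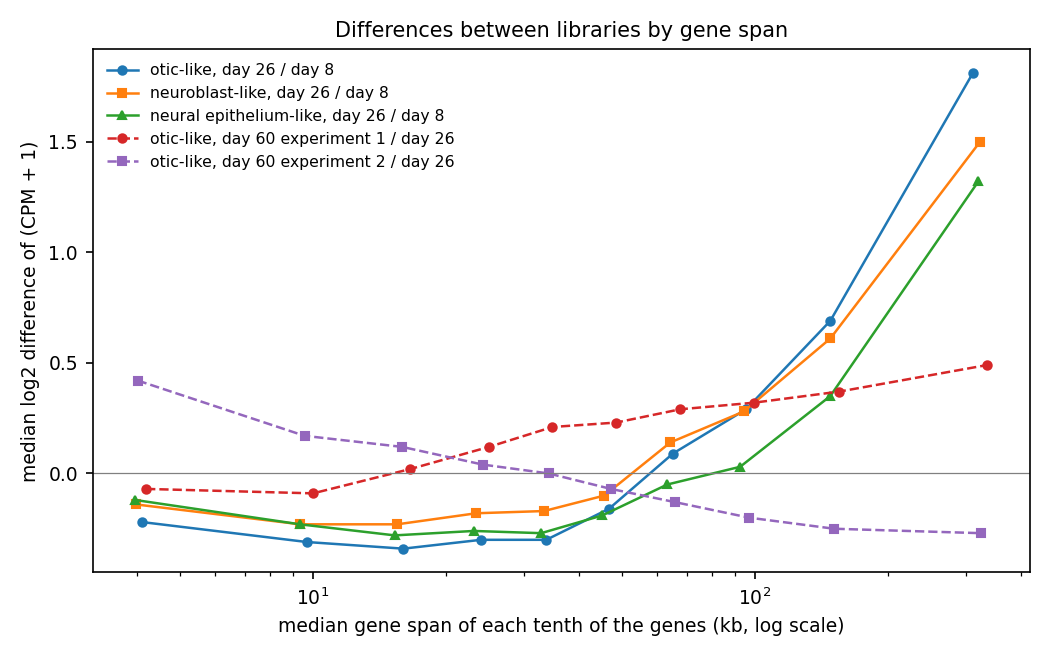
Median log2 difference of CPM + 1 (vertical axis) against median gene span (kb, logarithmic horizontal axis) in 10 groups of genes by span, for day 26 over day 8 (solid) and otic-like day 60 over day 26 (dashed). The longest genes are shifted upward at day 26 in all 3 classes shown.

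**Figure D3:**
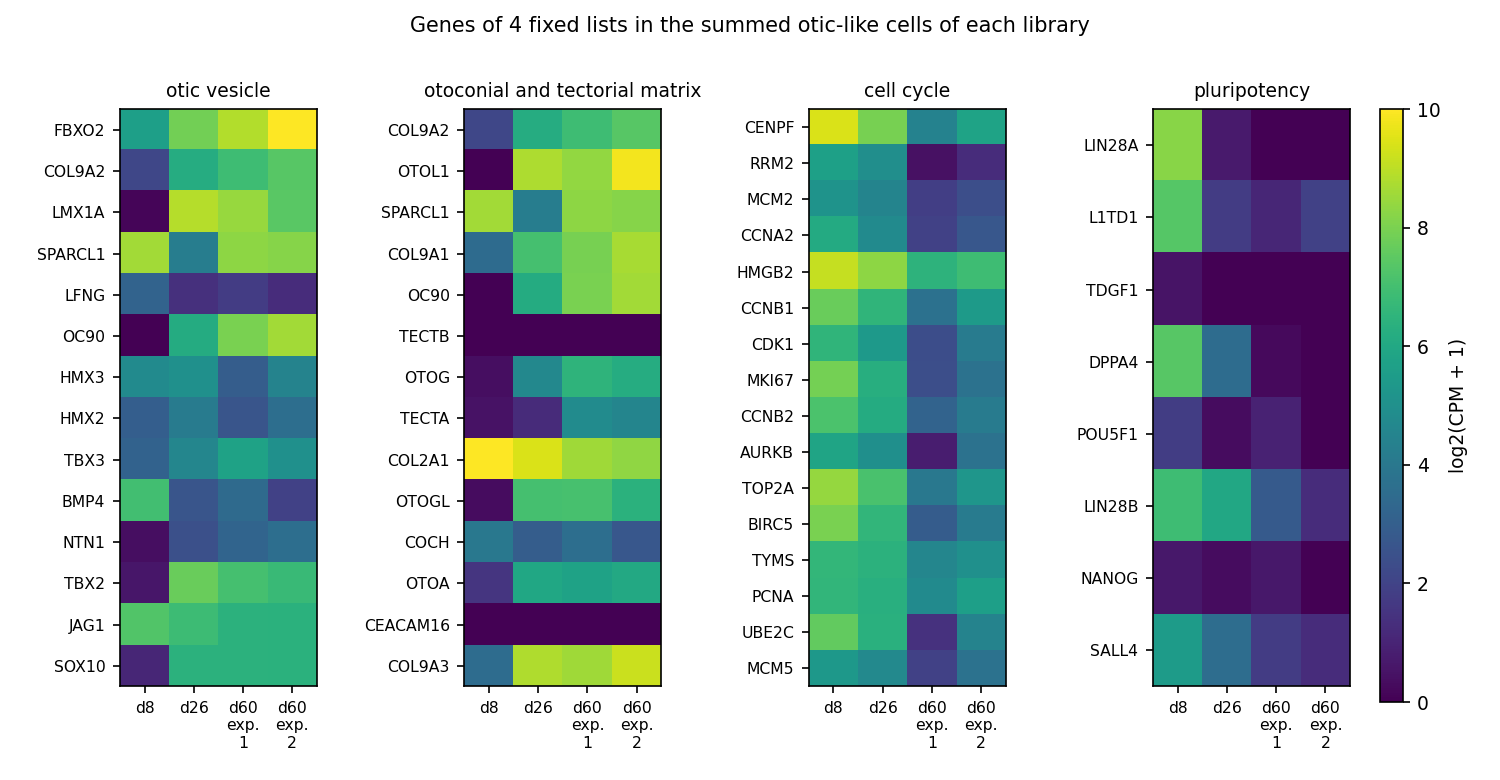
Level of the members of 4 gene lists in summed otic-like cells of each library (colour, log2 of CPM + 1). Most otoconial and tectorial matrix genes appear at day 26, and cell cycle and pluripotency genes fade after day 8.

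What changes in otic-like cells between the vesicle stage (day 26) and the sensory epithelium stage (day 60)? The lists that moved most in the day 60 pair were suprabasal and basal keratin genes and mesenchyme genes, which were higher, and cell cycle and pluripotency genes, which were lower. Some ion transport and matrix genes were higher by less. Placodal, otic vesicle and prosensory identity lists stayed close to their day 26 level. Of 10969 genes 196 were at least 4-fold higher and 72 at least 4-fold lower in both day 60 libraries (73.1% of 268 higher). Each alone gave 370 and 163 (experiment 1) and 403 and 225 (experiment 2), so more genes pass in either library than in both. Without the other library the count was 514 to 605, since genes that enter through the library left out then drop out. The all-gene median was 0.21 in experiment 1 and -0.03 in experiment 2, and the longest 10% of genes held 43 of the 196 higher genes (21.9%).

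PTGDS (ENSG00000107317), which encodes prostaglandin D synthase, went from 1.31 CPM at day 26 to 1300.8 and 3174.8 CPM (log2 9.14 in experiment 1 and 10.42 in experiment 2). MGP, an inhibitor of calcification, went from 1.47 to 216 and 135 CPM (6.46 and 5.79), and the secretory cell gene AGR2 from 1.24 to 121 and 419 CPM (5.76 and 7.55). Next came KCNH7 (5.58 and 5.66), CNTNAP2 (4.74 and 4.73), ECRG4 (4.63 and 5.27), MYH11 (4.41 and 4.84), COL3A1 (1.80 to 111 and 48.0 CPM), IGFBP7 (4.09 and 4.68) and SGCD (4.71 and 4.09). Lowest were MOXD1 (68.4 to 4.70 CPM in experiment 1 and 0 in experiment 2, at least 16.2-fold), LIN28B (-3.13; in experiment 2 a single count, 44.0-fold, 7.89 to 1738), DLGAP5 (-3.88 and -2.73), CENPK (-2.79 and -2.66), the BMP modulator BMPER (175 to 28.4 CPM; in experiment 2 with 2 counts 61.9-fold, 17.1 to 511), MKI67 (75.7 to 4.32 and 12.7 CPM), COTL1 (-2.47; with 2 counts 22.7-fold, 6.28 to 187), the BMP receptor gene BMPR1B (-2.46 and -3.29) and HMGA1 (275 to 37.8 and 49.4 CPM). The 87 otic-like cells of experiment 2 sum to 708707 UMIs, so 1 UMI there is 1.41 CPM.

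Cell cycle genes had a mean list median of -2.46 ± 0.80 (n = 2), with 14 of 16 members at least 2-fold lower in both, such as TOP2A (-3.12 and -1.90), CENPF (-3.51 and -2.14) and UBE2C (-4.94 and -1.89). Pluripotency genes stood at -2.70 ± 0.33 (3 of 4 lower). Endolymph ion transport genes stood at 0.91 ± 0.04 (4 higher, none lower), with the connexin genes GJB2 (1.70 to 22.2 and 26.8 CPM) and GJB6 (0.882 to 27.6 and 29.6 CPM), ATP1B2 (2.31 and 2.28) and SLC12A2 (1.04 and 1.05). Epidermis-like cells of day 60 also express both connexin genes (GJB2 25.7 and 114 CPM, GJB6 45.5 and 154 CPM), and their keratins are higher in the same otic-like sums, as given below. Otoconial and tectorial matrix genes stood at 0.91 ± 0.32 (4 higher, none lower), with TECTA (1.36 to 27.6 and 22.6 CPM), OC90 (69.7 to 251 and 387 CPM) and OTOG (1.82 and 1.51), and without naming members the median of both was 0.23 in place of 0.65.

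The placodal, otic vesicle and prosensory lists had medians of 0.09, 0.10 and 0.11, whose signs turn under other scalings. Inside them SPARCL1 (17.7 to 317 and 292 CPM), EYA4 (2.02 and 1.37) and FBXO2 (0.99 and 2.16) were higher and NGFR (-1.85 and -2.43) lower. Per library hair cell genes stood at 0.26 and 1.45, the latter with several members at 1 to 4 UMIs, neuroblast genes at 0.25 and -0.78, and NOTCH genes at 0.49 and 0.40. Dorsal patterning genes stood at -0.49 (GBX2 -2.87 and -3.11) and ventral ones at 1.31 in experiment 1 and -0.71 in experiment 2, with NR2F1 (2.69 and 2.00) higher and FST (-2.94 and -2.17) lower. Among signalling lists FGF response stood at -0.47 (DUSP6 -2.88 and -1.87), BMP response at 0.66 and -0.09 and WNT response at 0.74 and 0.04.

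Keratin genes were far higher: suprabasal 3.24 ± 1.09 (5 of 7 higher) with KRT13 (1.16 to 19.5 and 492 CPM) and KRT1 (2.48 and 6.97), and basal 1.82 ± 0.34 with KRT5 (1.58 to 40.0 and 143 CPM) and KRT17 (3.37 and 4.77), while simple epithelium genes stood at 0.20. Mesenchyme genes stood at 1.99 ± 0.80 (7 of 12 higher; DCN 12.6 to 159 and 102 CPM, COL1A1 2.60 and 1.47), dissociation genes at 1.28 ± 0.27 (JUN 1.93 and 3.06) and hypoxia genes at 1.27 ± 0.76 (VEGFA 3.69 and 1.74). COL3A1, MGP and IGFBP7 above are also high in mesenchyme. Mesenchyme-like cells made up 22.5% of experiment 1, where the mesenchyme list also stood at 1.97 in epidermis-like cells. Free RNA or mixed droplets are thus not set apart there. In experiment 2, with 1.31% such cells, the list stood at 1.42 in otic-like and -0.42 in epidermis-like cells. Tests that borrow the spread of the day 60 pair for all stages (1 residual degree of freedom) named 554 genes with edgeR (351 higher) and 315 with DESeq2 (223 higher). Summing all kept cells in place of the class gave 172 genes, a pseudocount of 10 CPM gave 49, and genes of at least 50 CPM gave 107.

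How do epidermis-like cells of day 60 differ from those of day 26, and from day 8? Day 60 cells expressed the suprabasal keratins and other genes of stratified epithelia, while pluripotency genes were lower in both libraries. Of 11057 genes 67 were at least 4-fold higher and 38 lower in both day 60 libraries (63.8% higher). The pair differed strongly from each other: experiment 1 alone gave 242 and 61, and experiment 2 alone 241 and 958, so leaving out a library turns the share higher to 79.2 or 20.7%. All-gene medians were -0.13 and -0.66, and with TMM scaling 111 genes passed, 80.2% higher. Against other genes the longest (at least 205 kb) were shifted by -0.93 log2 (-1.0 to -0.87) in experiment 2. In experiment 1 (at least 216 kb) the shift was 0.09 (0.05 to 0.13). In experiment 2 the median fell from 0.41 in the shortest genes to -1.5 in the longest. Of the 38 genes lower in both libraries 4 were long (at least 211 kb). With span taken out 115 genes passed, 80.9% higher. No epidermis-like class existed at day 8, so day 26 over day 8 was not computed.

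KRTDAP, a differentiation-associated keratinocyte gene, went from 2.37 CPM to 290 and 180 CPM (log2 6.43 and 5.74). KRT13, a keratin of wet stratified epithelia, went from 9.14 to 267 and 2952.3 CPM, followed by DUSP2 (from 2 counts; 167-fold, 46.0 to 1381, and 148-fold, 40.8 to 1221), LGALS7 (4.36 and 4.32) and EHF (4.19 and 5.62). Lowest were S100A1 (113 to 6.20 and 3.46 CPM), IGDCC3 (-3.61 and -5.37), SLC35F3 (-3.12 and -5.80), COL2A1 (-3.09 and -5.54) and FN1 (249 to 34.4 and 5.94 CPM). S100A1 and COL2A1 stood at 1785.4 and 686 CPM in day 26 otic-like cells, and neural epithelium-like cells of day 26 held 207 and 115 CPM. The otic-like share fell from 40.5% to 7.13 and 1.30%, so less free otic RNA at day 60 is not set apart from a change in the epidermis-like cells, for these genes or the otic lists below. The suprabasal list stood at 2.38 ± 0.32 (8 of 11 higher, none lower), with KRT4 (3.69 and 8.57), KRT10 (1.51 and 3.91), KRT1 (2.15 and 3.21) and LY6D (4.00 and 2.60). Of its members 5 also name the class, and without them the median of both was 1.53 in place of 2.68.

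Basal genes split (median -0.38, 3 higher, 1 lower; 0.34 and -0.63 per library), with KRT5 (1.75 and 1.89), KRT14 (2.23 and 1.26) and KRT15 (0.82 and 3.45) higher, and the sign turns with scaling. Dissociation genes stood at 1.76 ± 0.93 (FOS 127 to 473 and 2308.4 CPM, JUNB 2.22 and 4.65). Pluripotency genes were lower in both libraries (-2.16, all 5 lower), and cell cycle genes in experiment 1 (-1.76, against -0.23 in experiment 2). Several other lists were low in experiment 2, where the all-gene median is itself -0.66, and not or less so in experiment 1: otic vesicle (-0.04 and -1.85; 3 of 14 lower in both), otoconial (0.01 and -2.29), neuroblast (0.18 and -1.47), hair cell (0.16 and -1.06), FGF response (-0.18 and -1.63), ventral (-0.35 and -1.50), dorsal (-0.49 and -0.95) and placodal (-0.40 and -1.32; EYA1 267 to 91.4 and 4.96 CPM). Long genes were shifted down in experiment 2 as well, as given above, and these list values are not corrected for span. Mesenchyme genes were higher in experiment 1 (1.97) and lower in experiment 2 (-0.42), POSTN at 4.44 and 1.78. The libraries also went opposite ways for BMP response (0.19 and -1.17), prosensory (0.30 and -0.80), WNT response (0.74 and -0.97), NOTCH pathway (0.48 and -0.62), hypoxia (0.50 and -0.47), endolymph ion transport (0.15 and -0.46) and simple epithelium genes (-0.36 and 0.06). Without the shallow day 26 cluster 161 genes passed, with all kept cells 172, and with doublets left in 173, where the day 26 class went from 1099 to 442 cells.

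What separates neuroblast-like cells of day 26 from those of day 8? Day 26 cells had lower levels of the early neurogenic factors NEUROG1 and NEUROD4 and of ventral patterning and pluripotency genes. Much of the fall in neuroblast genes hangs on which clusters make up the class. Of 10199 genes 694 were at least 4-fold higher and 236 lower (74.6% higher). The longest 10% (span of at least 202 kb) held 373 of 693 higher genes (53.8%) and 7 of 236 lower ones (2.97%), and the shift was 1.55 (1.44 to 1.68). With span taken out 712 genes passed (397 higher, 55.8%).

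The highest genes given here all belong to these longest genes: ANKFN1 (0.887 to 906 CPM from 2 counts; 1021-fold, 283 to 8432), IL1RAPL1 (to 645 CPM from a single count; 1454-fold, 261 to 57431), the cell adhesion gene CNTN5 (0 to 170 CPM; at least 127-fold) and LRP1B (to 267 CPM; 301-fold, 83.3 to 2489). Lowest were LIN28A (226 to 0.575 CPM, -7.17), HAPLN1 (-6.52), ONECUT1 (202 to 2.49 CPM, -5.86), the retinoic acid binding gene CRABP1 (2336 to 42.7 CPM, -5.74) and CLDN5 (-5.70).

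Of 14 neuroblast genes 9 were at least 2-fold lower (median -1.22), among them NEUROG1 (241 to 38.7 CPM, -2.61), NEUROD4 (320 to 47.9 CPM, -2.72), STMN2 (380 to 91.4 CPM, -2.04), NHLH1 (-1.45), POU4F1 (-1.40) and ISL1 (-1.13), with NEUROD1 unchanged (497 to 521 CPM). Of them 12 also name the class. Day 26 cluster 18 (318 cells), nearest to neuroblast-like cells but left unnamed, was rich in STMN2 (1052 CPM). With it in the class the neuroblast list stood at -0.10 and STMN2 at 404 CPM (0.09), NHLH1 at -0.55, POU4F1 at -0.67 and ISL1 at -0.29, while NEUROG1 (-2.71) and NEUROD4 (-2.21) stayed low. Cell cycle genes had a median of 1.02 (9 higher, none lower, percentile 100.0), with UBE2C (1.79), TOP2A (1.27) and MKI67 (88.7 to 181 CPM, 1.02). With cluster 18 in the class the median was 0.61, UBE2C (1.37) alone of the members stayed at least 2-fold higher, and MCM2 (-0.36) and MCM5 (-0.32) were lower, so this rise also hangs on the class. The otoconial and otic vesicle lists stood at 3.17 (9 higher) and 1.95 (8 higher, 4 lower), with EYA1, a placodal gene (18.2 to 453 CPM, 4.56), SPARCL1 (35.5 to 653 CPM, 4.16) and S100A1 (5.71) higher and BMP4 (-4.67) lower. Much of the otoconial list stood far below its level in day 26 otic-like cells, which make up 40.5% of that library: OTOL1 at 48.8 against 431 CPM, OTOGL at 14.3 against 130 and OC90 at 13.3 against 69.7, as did LMX1A at 30.7 against 468 and TBX2 at 27.6 against 211. Neural epithelium-like cells of day 26 held 19.4 CPM of OTOL1 and 7.09 of OC90, so free RNA or mixed droplets are not set apart for these genes. Among genes of at least 50 CPM the otic vesicle median turned to -1.49.

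Hair cell genes stood at 1.08 (10 of 16 higher; PCDH15 3.95). Ventral patterning genes stood at -1.65 (7 lower; OTX1 -4.23, OTX2 -3.91), pluripotency at -2.45 (DPPA4 -3.65) and placodal genes at -0.28 (3 higher, 7 lower, percentile 10.4; -1.65 without naming members). NOTCH genes stood at 0.01, with the ligand genes DLL1 (-3.82), DLL3 (-2.34) and JAG1 (-1.49) lower and JAG2 at 0.46. Medians of the other lists were 0.57 for hypoxia, 0.46 for endolymph ion transport, 0.13 for dissociation, 0.00 for BMP response, -0.10 for dorsal patterning, -0.11 for prosensory, -0.36 for basal epidermis, -0.44 for FGF response, -0.49 for WNT response, -0.52 for simple epithelium and -0.74 for mesenchyme genes. With a pseudocount of 10 CPM 321 genes passed, and 398 among genes of at least 50 CPM. The day 8 class is a single cluster of 161 cells.

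**Figure D4:**
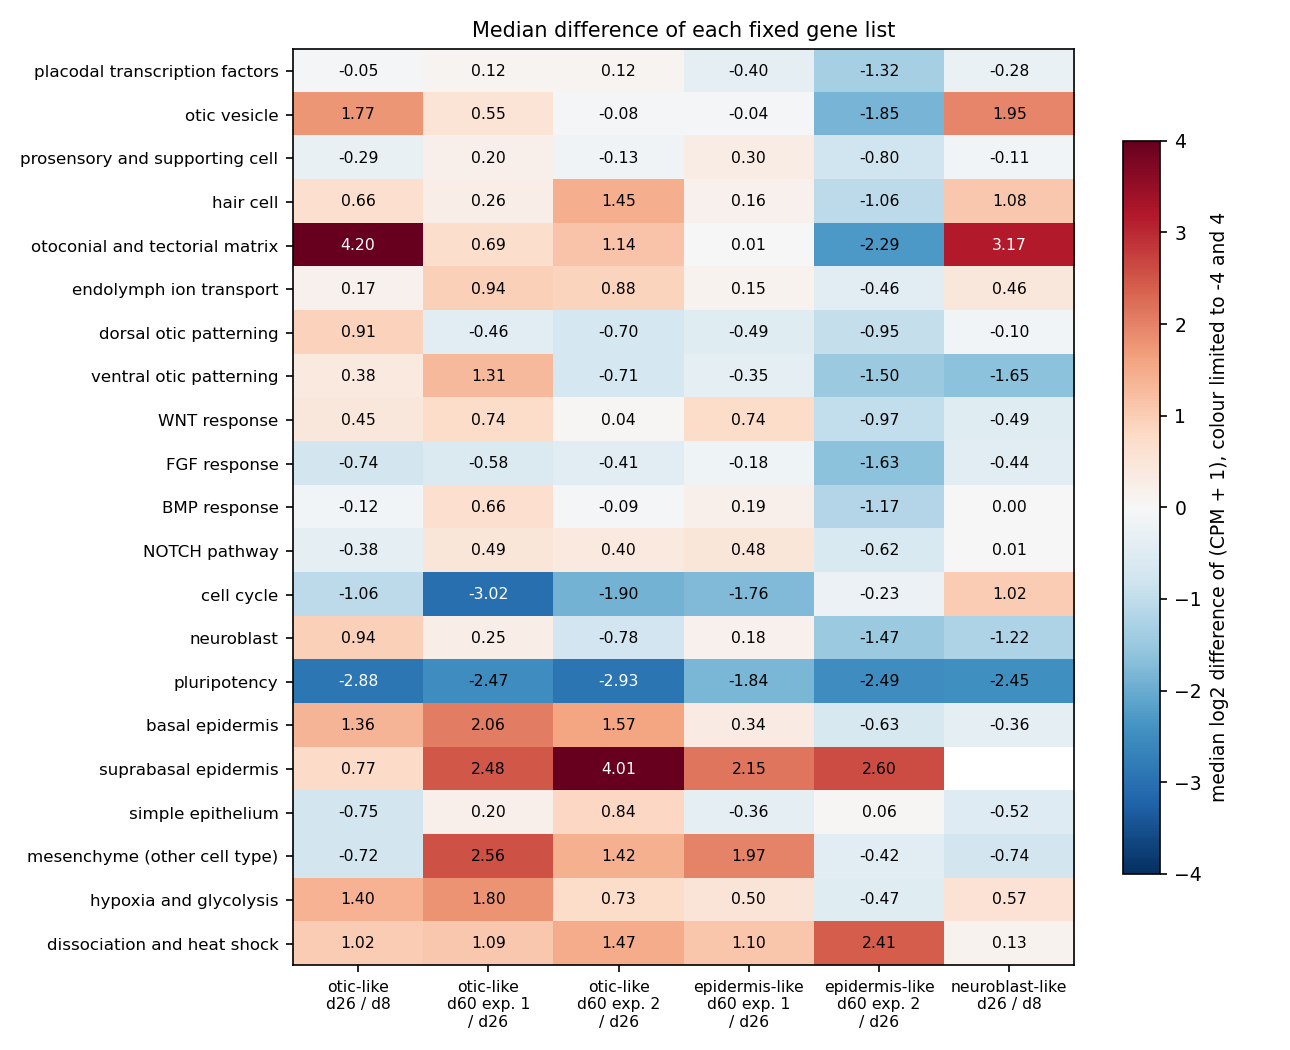
Median log2 difference of CPM + 1 per gene list (colour and printed value) for the stage comparisons in columns, with each day 60 library on its own. Cell cycle genes are lower in otic-like cells at both steps.

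How do the otic-like cells of the selected organoids (experiment 2) differ from those of the unselected ones (experiment 1) at day 60? Experiment 2 sums held far more of the suprabasal keratin and calprotectin genes, and less of ventral patterning, mesenchyme and hypoxia genes. Of 10657 genes 97 were at least 4-fold higher and 234 lower (29.3% of 331 higher); the all-gene median was -0.22, and with TMM scaling 292 passed, 42.5% higher. The longest 10% of genes held 79 of the 234 lower genes (33.8%), and with span taken out 267 genes passed, 41.9% higher. A few cells carry the keratin value: 9 of the 87 experiment 2 cells held 75.3% of its suprabasal UMIs other than KRT10, which other classes also express, and the median cell had 1 against 0 in experiment 1. Highest were S100A9 (3.57 to 656 CPM, 7.17) and S100A8 (13.1 to 732 CPM, 5.70), which encode calprotectin, and the keratin genes KRT4 (0.751 to 104 CPM, 5.91), KRT13 (19.5 to 492 CPM, 4.59) and KRT1 (6.95 to 178 CPM, 4.49). The lowest was the choroid plexus gene TTR (203 to 0 CPM, at least 48.0-fold), whose level in otic-like cells of experiment 1 lies below that of the library outside its ciliated-like cells (1197.5 CPM, and 71485.3 CPM in these), so free RNA is not set apart there. Next were RELN (148-fold, 26.5 to 5852), the neurotrophin receptor gene NTRK2 (72.6-fold, 13 to 2871), NELL1 (235 to 7.06 CPM, -4.87) and SLC8A1 (28.0-fold, 7.69 to 232), with at most 2 counts each in experiment 2 for RELN, NTRK2 and SLC8A1. All 4 lie in the longest 10% of genes, and NELL1 turned sign with doublets left in. When the experiment 1 class was clustered again, NELL1 and RELN were the top genes of an unnamed subcluster of 34 cells.

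Suprabasal genes had a median of 1.71 (6 of 7 higher), cell cycle 1.23 (9 higher, MKI67 on 9 counts in experiment 2), dissociation 0.74 and simple epithelium 0.72. Ventral patterning stood at -1.90 (7 lower), hypoxia at -1.27, mesenchyme at -1.16 (8 lower), neuroblast at -1.09 and WNT response at -0.92 (5 lower). The neuroblast value rests on few UMIs. NEUROD1 had 6 counts in experiment 1 (1.13 CPM) and 0 in experiment 2, where 1 UMI is 1.41 CPM, though STMN2 had 82 counts (15.4 CPM) and 0. Mesenchyme-like cells made up 22.5% of experiment 1 and 1.31% of experiment 2, so free RNA is not set apart for the mesenchyme list. The cell cycle value has no support from MKI67 detection, whose intervals overlap as given above. Otic vesicle (-0.04) and otoconial (0.09) genes did not differ as groups. Hair cell genes (0.93) rest on few UMIs in experiment 2, several on 1 to 4, where a single UMI passes as 2-fold. Each side is a single library, the experiments also differ in number of organoids, and the experiment 2 sum rests on 87 cells. With CP10k means over cells 597 genes passed (18.1% higher), with doublets left in, which also changed the experiment 1 class from 448 to 172 cells, 458 (45.4% higher), and with a pseudocount of 10 CPM 56.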

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

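The tests per library of the keratin genes, leaving KRT10 out of them, and the neuroblast-like class with an unnamed cluster added, were chosen only after the result was seen. Some changes from day 8 to day 26 ran in opposite directions in the otic-like and the neuroblast-like cells. The cell cycle list had a median of -1.06 in otic-like and 1.02 in neuroblast-like cells. SPARCL1, which encodes a secreted matrix protein, stood at -4.4 and 4.16, and STMN2, a gene of young neurons, at 2.46 and -2.04. None of these differences was tested, since each stage has 1 library. The STMN2 contrast depends on the class: with day 26 cluster 18, nearest to neuroblast-like cells but unnamed, STMN2 stood at 0.09, SPARCL1 at 3.67 and the cell cycle list at 0.61 in neuroblast-like cells. MKI67 detection at equal depth went from 23.4 to 9.93% of otic-like and from 10.7 to 18% of neuroblast-like cells, the latter without cluster 18. MKI67 is a member of the list and was read in the same cells, so this is no separate support. The intervals of the neuroblast-like cells also overlap, as given above.

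Cells with at least 6 of the 16 hair cell markers also turned up in clusters that bear no class name and enter no comparison. They were 6.92% of cluster 18 at day 26 (22 of 318 cells), 0.903% of cluster 2 (4 of 443) and 1.08% of cluster 8 (4 of 369) in day 60 experiment 1, and 5.26% of cluster 12 in experiment 2 (9 of 171). A count of 0 would allow up to 0.943, 0.677, 0.813 and 1.75%. Over all kept cells the share was 0.399% at day 26, 1.58% in experiment 1 and 0.164% in experiment 2, so clusters 2 and 8 lie below their own library and show nothing. The named hair cell-like cluster reached 38.5% (25 of 65 cells). Cell types outside the ear reached it too, ciliated-like cells with 15.9% and choroid plexus-like cells with 7.04%.

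The keratin genes of stratified epithelia were far higher in day 60 than in day 26 otic-like cells, and the libraries gave different readings. KRT10 was left out since it is expressed widely (2.35 UMIs per day 8 otic-like and 2.51 per day 26 mesenchyme-like cell). With it the ratios below were 0.654 and 3.47. In experiment 1 otic-like cells held 1.66 (1.47 to 1.89) times as many suprabasal UMIs per cell as mesenchyme-like cells (0.853 against 0.513, the latter 0.0533 at day 26), so RNA from lysed epidermis-like cells is a candidate source there. In the same library 68.8% of the UMIs sat in the 45 richest of 448 cells against a random upper bound of 45.8%, so epidermis-like cells or mixed droplets inside the cluster are a candidate source as well. In experiment 2 the ratio was 5.18 (4.24 to 6.37), which argues against free RNA as the whole source. There 75.3% of the UMIs sat in 9 of 87 cells (random upper bound 31.4%), as whole cells or mixed droplets would give. The stage itself stays open as untested.

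Long genes made up 53.5% of the genes higher at day 26 in otic-like cells. If introns were counted at day 26 and not at day 8, long genes would be shifted up in every cell type. The shift was 1.45 (1.35 to 1.57) in neural epithelium-like, 1.55 (1.44 to 1.68) in neuroblast-like and 1.94 (1.80 to 2.08) in otic-like cells. Introns may thus be a source, but the shift was larger in otic-like cells than in the other classes. Shallow droplets rich in nuclear RNA are argued against as the whole source, since without the shallow day 26 clusters the otic-like shift was 1.76 (1.63 to 1.93). Both file headers for these stages give the same Cell Ranger version, and the stage difference itself stays open as untested.

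At day 26 26.1% of cells had under 0.5% mitochondrial UMIs, and these carried genes of the integrated stress response: GDF15 at 192 against 10.5 CPM in other cells, TRIB3 158 against 14.9, DDIT3 182 against 42.8 and ATF5 254 against 49.2, with cell cycle genes at -2.13. Bare nuclei are argued against, since ribosomal protein genes took a larger share of UMIs (1.33 times, 36.1 against 27.0%). Stress from dissociation cannot be told apart, because the list's median was 0.21 with a resampling interval of -1.04 to 0.52. No biological explanation was tested.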

How the results depend on the processing

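Depth limits the day 60 sums, with 1 UMI at 1.41 CPM in experiment 2, and no paired analysis was possible because the labels give no number that joins libraries. Chosen after seeing the data were the span correction, leaving out low-mitochondrial cells, the shallow day 26 cluster, cells with suprabasal UMIs or class-naming list members, counting cells with at least 6 hair cell markers, adding to a class the unnamed clusters nearest to it, and the alternatives for experiment 2 over 1. For every change below the cause was not tested, apart from fewer genes entering at 50 CPM.

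Otic-like shares at day 8, day 26 and epidermis-like shares at day 26 were 33.5, 36.7 and 5.44% with at least 1000 genes and at most 10% mitochondrial UMIs. At most 25% gave 23.3, 37.3 and 10.4%, and no doublets removed 27.9, 42.6 and 2.97%. Leiden resolution 0.5 gave 32.5, 43.3 and 2.64%, resolution 2 gave 24.6, 35.2 and 10.8%, and joint clustering 23.2, 25.4 and 10.1%. Naming cell by cell gave 4.08, 30.7 and 3.42%, and without low-mitochondrial cells 27.1, 52.8 and 7.35%. Day 60 mean shares ran from 1.41 (at most 25% mitochondrial UMIs) to 4.37% (otic-like) and from 34.0 to 53.4% (epidermis-like), and the SD of 2 libraries is too wide to call them stable. Hair cell-like cells numbered 89, 290, 113 and 29 (day 8, day 26, day 60 experiments 1 and 2) when named cell by cell, 3, 56, 99 and 11 by at least 6 markers, and 0 in experiment 1 with joint clustering. EPCAM was detected in 50.2, 70.6, 18.2 and 53.1% at 4000 UMIs and 65.8, 80.7, 27.6 and 58.0% unthinned.

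With a pseudocount of 10 CPM the gene counts were 423 (otic-like, day 26 over day 8), 49 (otic-like, day 60 over day 26), 21 (epidermis-like), 321 (neuroblast-like) and 56 (experiment 2 over 1), and 14 list medians had a size of at least 1 in place of 33. With genes of at least 50 CPM the first 4 were 504, 107, 49 and 398. All kept cells gave 172 for otic-like day 60, 172 for epidermis-like and 45 list medians in place of 27. edgeR gave 554. No doublets removed gave 173 and no shallow cluster 161 for epidermis-like cells. Mean CP10k gave 597 for experiment 2 over 1. Leaving out a day 60 library gave 514 to 605 (otic-like), 293 to 1146 (epidermis-like) and 14 to 20 list medians in place of 13.

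Among named genes and lists with a median of at least 1 in size these turned sign: with all kept cells the hypoxia list in otic-like day 60 over day 26 (-0.21), and in neuroblast-like cells the cell cycle (-1.18) and neuroblast (1.59) lists and CRABP1 (0.62), with SLC35F3 (0.24) and FN1 (0.49) in epidermis-like cells. With genes of at least 50 CPM the neuroblast-like otic vesicle list did (-1.49), and with no doublets removed NELL1 (0.78) in experiment 2 over 1. Of 159 main results under alternatives 63 moved and 96 did not. Moved means outside the counting interval (single libraries), outside mean ± SD (day 60 shares) or beyond 1.5-fold (gene, list and hair cell counts). The wide day 60 SD and hair cell counts that stayed at 0 lift the number that did not move. For lists 725 of 1208 moved and 479 did not. Only comparisons of both day 60 libraries with day 26 had an SD to judge lists by. Elsewhere every list counted as moved or reversed at any value, so 725 is no measure of stability. For named genes 147 of 830 moved by a log2 of at least 1 and 679 did not. Detection moved in 24 of 24, which is no test, since it was read at greater depth than the interval at 2000 UMIs.

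With unnamed clusters added to the class nearest, 945, 261, 112 and 1068 genes passed (otic-like, otic-like day 60, epidermis-like, neuroblast-like), but the neuroblast list in neuroblast-like cells went from -1.22 to -0.10. TMM put the share higher at 75.2% (otic-like, day 26 over day 8), 65.0% (otic-like, day 60), 80.2% (epidermis-like) and 42.5% (experiment 2 over 1). Not computed were otic-like day 60 at resolution 0.5 (0 such cells in experiment 2), otic-like cells free of suprabasal UMIs (12 cells there, or 38 with KRT10 not counted), every epidermis-like day 26 over day 8 alternative, and the neuroblast list without class-naming members.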

Other observations

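The clusters and genes of this part, and its values, were chosen after they were seen. The 65 hair cell-like cells of day 60 experiment 1 expressed the hair cell transcription factors POU4F3 (141 CPM), ATOH1 (85.4), LHX3 (51.6) and GFI1 (20.6), the synaptic gene OTOF (84.7), the hair bundle gene CDH23 (81.8), and CCER2 (1313.3) and PCP4 (1096). They also held the neuronal differentiation genes NEUROD1 (489) and INSM1 (119). The mechanotransduction channel gene TMC1 was at 6.63 CPM. Genes they shared with day 26 clusters 13 and 18 were ANKFN1 (1103.4 CPM here, 1400.5 in cluster 13 and 1268.8 in cluster 18), KCNB2 (1280.1 here, 369 and 1144.6), AGBL1 (368 here, 137 and 944) and THSD7B (1442.2 here, 1116.9 and 2907.1), while ATOH1 had no count in either of these. The other neuroblast-like day 26 cluster, 15, had less ANKFN1 (146), with ATOH1 at 3.16 (13 counts) and POU4F3 at 14.8 CPM. Otic-like cells of the same library stood at 6.01 CPM for ANKFN1 and 0.939 for POU4F3. Cluster 12 of experiment 2, which has no class name, mixed muscle (ACTC1 1078.9, MYLPF 700), choroid plexus (TTR 2087.7) and hair cell genes (PCP4 319, CCER2 106, POU4F3 19.5, ATOH1 10.1).

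Small clusters carried further programmes. At day 26, 132 cells (0.94%) had interferon response genes (ISG15 1519.3 against 53.9 CPM in all other cells, IFIT1 481 against 6.62), 29 cells had podocyte genes (NPHS1 398 against 1.37, WT1 200 against 0.216) and 40 cells pigment and glial genes (PMEL 737, S100B 659). In day 60 experiment 1, 48 cells had bone genes (IBSP 26130.7 against 21.7 CPM, SOST 927, DMP1 458), 34 cells pigment genes (DCT 5325.3, TYRP1 3493.5), 145 ciliated-like cells TTR at 71485.3 CPM, 62 chondrocyte-like cells the cochlear cartilage gene OTOR (481) beside OTOL1 (251), and 369 cells the arrest gene CDKN1A (420 against 53.5) with GDF15 (430). In experiment 2, 465 cells had airway secretory genes (LCN2 1063.3 against 7.45, SCGB1A1 244 against 2.15), 82 cells tuft cell genes (POU2F3 326 against 31.0, KIT 290, IL23A 191) and 420 cells hypoxia genes (CA9 246 against 37.8).

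Low-mitochondrial cells with stress genes were also found at day 60, where GDF15 stood at 329 against 23.9 CPM in experiment 1 (22% of cells) and 396 against 47.6 in experiment 2 (8.61%). At day 8 they made up 7.28% and GDF15 did not differ (2.74 against 3.43 CPM). At day 26 78.4% of them lay in clusters without a name and 5.67% were otic-like.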
